A study of Mus musculus with 6 samples.

How the data were processed

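RNA sequencing libraries of 6 samples from female C57BL/6 mice were analysed, 3 labelled vehicle and 3 labelled rMANF (recombinant mesencephalic astrocyte-derived neurotrophic factor). The labels give the tissue as heart and call the 3 samples of each group biological replicates, read here as separate mice. Per the labels' protocols, B16F10 cells, a transplantable mouse melanoma line, were placed under the skin of the flank, and daily intraperitoneal injections of phosphate-buffered saline or rMANF at 2 µg/kg followed once tumours averaged about 60 mm3, with 8 mice randomised per group. How the 3 libraries per group were chosen from the 8 mice is not given in the sources used here. The labels also give a column name for each sample, and those of the vehicle samples begin with IgG although their treatment is given as phosphate-buffered saline.

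Per the labels' protocols, total RNA was extracted with QIAzol and libraries were made from cDNA with the Nextera XT kit, which does not mark strand. Per the submitters' processing notes, cutadapt, fastp, Salmon 0.14.1 and HTSeq 0.11.0 were used with mouse build mm10. Which of these tools gave the final values, the annotation and any filter on low values are not given in the sources used here. The authors deposited log2 TPM (each transcript as a share of its library, corrected for length) per gene and library in 1 table of 23494 genes. Raising 2 to the deposited log2 values gave sums within 19.5 TPM of the full TPM scale in every library, so no offset had been added before the logarithm. A deposited value of −9 stood for a gene with no estimate and was set to 0 TPM. The table held 0 columns of other samples.

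TPM is a share of each library and keeps no record of read number, so the depth per library is unknown and no counting interval or floor was computed. The precision stated is that of the spread between mice. A change of abundant transcripts shifts the share of all others, and the scaling alternatives address this.

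Differences were computed as rMANF minus vehicle on log2(TPM + 1), which understates changes of low genes. The 12865 genes with a mean of at least 1 TPM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (linear model without covariates, empirical Bayes variances with a mean trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. For single values an exact two-sided permutation test over the 20 assignments of 3 against 3 libraries was added, whose smallest possible p is 0.1. Beside these, genes were counted whose 3 values in each group did not overlap, which chance gives for 10% of genes.

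Before the data were examined, 48 gene lists were fixed, covering pathways and markers of the cell types a heart sample could hold. The 42 lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 42 lists. Camera with a correlation estimated from the data, and fry, which asks whether the members move 1 way on balance, were run beside it. The other 6 lists had fewer than 5 tested members and were not tested. For each list the number of members that passed limma's test adjusted over the list alone was counted too.

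The genes named were also set by a rule fixed beforehand. They are Manf and genes of its family, binding partners and receptors of interest (always), and, since no gene passed the threshold, the 10 non-overlapping genes of smallest p in each direction, leaving out predicted gene models, Rik clones and pseudogenes. Of those that lay higher, 1 is not reported here. For each list described, up to 3 members of smallest p are given as values. The rule also set the 2 members with the highest mean TPM per library for lists of other cell types. These are reported for the neutrophil and skeletal muscle lists. Genes used to describe the tissue itself were chosen after their values had been seen.

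Gene coordinates and transcript GC content came from GENCODE M21 on GRCm38, the assembly named mm10. GC content was found for 12830 of the 12865 tested genes (99.7%). The alternatives tried were pseudocounts of 0.1 and 5 TPM, no filter or a filter at 5 TPM, 3 other scalings (median of ratios, quantile, and rescaling without mitochondrially encoded and haemoglobin genes), variances without trend or robust, library weights, the replicate number as a block, each library left out, a threshold of 0.10, a minimum log2 difference of 1, and camera on ranks. Chosen after seeing the data were removal of each library's GC trend (loess, span 0.5), alone and with the block, the skeletal muscle level as a covariate, and leaving out vehicle replicates 1 and 2 together.

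The procedure was tested on simulated data with 12865 genes and 3 against 3 libraries. Of 200 genes changed by 1 on the log2 scale it recovered 97.2% over 5 runs, with 3.75% of calls false. Of 200 changed by 2 it recovered 99.8%, with 6.63% of calls false. Changes were planted only in genes with a mean log2(TPM + 1) above 3, with normal noise drawn independently for each gene. These shares thus do not extend to lower genes or to spread shared between genes. In simulated data without changes camera called 0.15 lists on average over 20 runs. Members of a list varied independently there, so 0.15 is no false-call rate for lists whose members vary together. Other splits of the real libraries into 3 and 3 gave 8 to 20 called lists.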

Results

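The series asked how injections of rMANF, the recombinant form of an endoplasmic reticulum protein that is also secreted, alter gene expression in the hearts of mice carrying B16F10 melanoma. Whole-transcriptome expression was measured in 6 libraries labelled heart, each from a separate sample of a female mouse, 3 treated with vehicle and 3 with rMANF. The values are TPM, so sequencing depth is unknown. Between 18830 and 19298 of the 23494 listed genes had a value above 0 TPM in a library, and Spearman correlations between libraries, across genes, lay between 0.938 and 0.952. Vehicle replicate 3 correlated more closely with each rMANF library (0.947 to 0.950) than with vehicle replicates 1 (0.943) and 2 (0.944). The first principal component held 38.5% of the variance and placed all 3 rMANF libraries on 1 side of the vehicle libraries. The second held 25.2% and set vehicle replicate 1 (34.7) apart from the other 5 libraries (−19.4 to −1.06).

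The libraries labelled heart held very little RNA of heart muscle cells. The atrial peptide gene Nppa reached at most 0.541 TPM in any library, cardiac actin Actc1 at most 0.905 TPM and phospholamban (Pln) at most 0.0432 TPM. Nppb, a natriuretic peptide gene like Nppa, went the other way at 46.6 to 57.4 TPM in all 6 libraries. Atrial cardiomyocyte markers, 18 of 20 with rows, summed to 106 to 149 TPM per library, with a median member at 0.735 TPM. Summed over 9 genes of the cardiac contractile apparatus and myoglobin (Actc1, Tnnt2, Tnni3, Tnnc1, Myl2, Myl3, Mybpc3, Ttn and Mb), expression was 31.9 ± 32.4 TPM in the vehicle libraries and 9.72 ± 2.05 TPM in the rMANF libraries (SD, n = 3 each), against 4864 to 6047 TPM for the single housekeeping gene Gapdh. Myh6, Ryr2 and Nkx2-5, cardiac genes too, were not among the rows analysed here. Genes of dividing cells were abundant: the 35 cell cycle genes summed to 3202 ± 122 TPM with vehicle and 3161 ± 63.1 TPM with rMANF, and Ube2c, which drives exit from mitosis, reached 426 to 518 TPM. The intermediate filament gene Vim reached 2969 to 4246 TPM, and the homeobox genes Rhox5 and Esx1 712 to 793 and 336 to 482 TPM. The melanosome gene Pmel reached at most 0.341 TPM. Because these levels go against the tissue label, the libraries are called libraries labelled heart, vehicle or rMANF, and every direction given here rests on those labels.

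**Figure D1:**
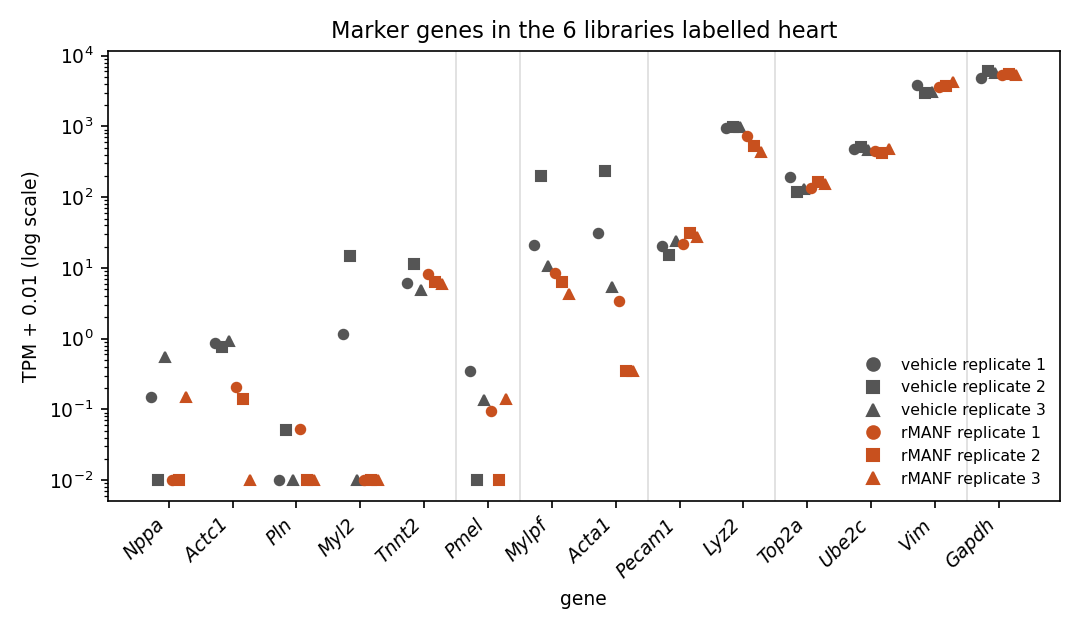
TPM plus 0.01 on a log axis for 14 genes in each of the 6 libraries labelled heart (grey, vehicle; orange, rMANF; symbol shape, replicate number). Genes of heart muscle (Nppa to Tnnt2) and pigment (Pmel) lie at least 2 orders of magnitude below Vim and Gapdh, and the skeletal muscle genes Mylpf and Acta1 are highest in vehicle replicate 2.

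The injected protein's own transcript lay slightly lower in the libraries labelled rMANF. Manf (chromosome 9, 106838312 to 106891979, GRCm38) measured 93.1 ± 12.3 TPM with vehicle and 77.7 ± 2.52 TPM with rMANF (SD, n = 3 each), with no overlap between groups and a log2 difference of −0.25 ± 0.11 (SE), which did not pass limma's test (Benjamini-Hochberg adjusted p = 0.238). The Manf difference was −0.16 without vehicle replicate 1 and −0.06 without vehicle replicates 1 and 2 together. Hspa5, the endoplasmic reticulum chaperone that MANF binds, measured 478 ± 84.8 and 470 ± 37.1 TPM, a log2 difference of −0.01 ± 0.13 (limma, adjusted p = 0.972) whose sign turned under quantile normalization (0.03). Nptn, which encodes neuroplastin, a reported MANF receptor, differed by −0.12 ± 0.09, and the KDEL receptor genes Kdelr1, Kdelr2 and Kdelr3, whose products retrieve resident proteins to the endoplasmic reticulum, by 0.08 ± 0.08, −0.14 ± 0.08 and −0.21 ± 0.11. Over the alternatives tried Nptn ran from −0.22 to −0.01, Kdelr1 from 0.03 to 0.13, Kdelr2 from −0.20 to −0.11 and Kdelr3 from −0.28 to −0.06. Without vehicle replicate 1 Nptn stood at −0.07 and Kdelr1 at 0.12. Cdnf, the paralogue of Manf, and the oestrogen receptor gene Esr1 were too low to test, at 0.644 ± 0.144 against 0.861 ± 0.262 TPM and 0.420 ± 0.0808 against 0.247 ± 0.0794 TPM. Esr2 was not among the rows analysed here. The 28 measured genes of endoplasmic reticulum chaperones and the unfolded protein response had a median log2 difference of −0.02 and were not called by camera (adjusted p = 0.517; 0.852 with an estimated correlation). Within that list Sec11c, of the signal peptidase complex, lay lower (148 ± 16.1 and 97.7 ± 6.28 TPM), and the chaperone gene Hyou1 and the ubiquitin ligase gene Syvn1 lay higher (52.8 ± 4.66 and 63.8 ± 1.4, and 29.6 ± 1.83 and 35.3 ± 0.242 TPM). Over all genes 0 members passed limma's threshold, and 1 passed adjusted over the list alone.

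Genes of macrophages, chemokines and MHC class II presentation lay lower in the libraries labelled rMANF than in those labelled vehicle. All rMANF values lay below all vehicle values for 15 of 33, 11 of 29 and 6 of 10 measured members. Over all 12865 tested genes this held for 1160. All rMANF values lay above all vehicle values for 2, 1 and 0 members of these lists and for 2436 of all tested genes. These 3 lists were called by camera with its preset correlation (adjusted p = 1.72e-12, 3.22e-10 and 2.89e-06). With an estimated correlation camera called none of them (adjusted p = 0.519 for each). The chemokine genes Ccl3, Ccl4 and Ccl8 measured 35.4 ± 8.12, 70.2 ± 13 and 727 ± 176 TPM with vehicle and 8.70 ± 2.63, 35.4 ± 1.06 and 262 ± 44.7 TPM with rMANF (SD, n = 3 each). Mitochondrially encoded transcripts also lay lower, and endothelial markers lay higher (camera, adjusted p = 5.80e-11 and 0.00170; adjusted p = 0.519 and 0.526 with an estimated correlation). No single gene passed the threshold of 0.05, the lowest adjusted p being 0.0893.

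Of the 12865 genes, limma called 0, although 2642 had an unadjusted p under 0.05 where chance gives 643, and the groups did not overlap for 3596 (27.9%, where chance gives 10%). Of the 2642, 67.7% lay higher with rMANF, a share that was 52.0% under median-of-ratios scaling and 57.7% under quantile normalization, so the split between directions depended on the scaling. At an adjusted p threshold of 0.10 limma called 351 genes, 249 higher and 102 lower (70.9% higher, and 60.4% under median-of-ratios scaling). That count was 971, 0 and 538 without vehicle replicate 1, 2 or 3 and 3, 0 and 0 without rMANF replicate 1, 2 or 3. It was also 0 after rescaling without mitochondrial and haemoglobin genes, without the variance trend or with the skeletal muscle level as a covariate. It was 1 without the filter on low values or with each library's GC trend removed. The highest count was 1859, with library weights. At 0.05 leaving out vehicle replicate 1 gave 4 genes and leaving out rMANF replicate 1 gave 2, all predicted gene models.

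The 10 non-overlapping genes of smallest p that lay lower were, in that order, Clec4n, Ccl3, Wfdc17, Ccl8, Ccl4, Mmp13, Crabp1, Fcer1g, Ccdc152 and Ch25h, each with a limma Benjamini-Hochberg adjusted p = 0.0893. Ccl3 (chromosome 11, 83647844 to 83649355), Ccl4 (83662584 to 83664683) and Wfdc17 (83703991 to 83706268) are neighbours, and Ccl8 (82115185 to 82116799) lies on the same chromosome. Ccl3 had the largest of these differences at −1.91 ± 0.22 on the log2 scale (SE), followed by Crabp1, a retinoic acid binding protein gene, at −1.48 ± 0.21 (11 ± 1.82 and 3.38 ± 1.25 TPM) and Ccl8 at −1.45 ± 0.20. Clec4n, which encodes the myeloid lectin receptor dectin-2 (chromosome 6, 123229843 to 123247021), measured 47.0 ± 1.85 and 28.3 ± 1.26 TPM, and Fcer1g, the signalling chain of Fc receptors, 576 ± 70.5 and 314 ± 45 TPM. Wfdc17 measured 360 ± 42.7 and 196 ± 14.7 TPM, the collagenase gene Mmp13 48.8 ± 6.21 and 27.1 ± 2.17 TPM, Ch25h, which makes 25-hydroxycholesterol, 21.8 ± 3.00 and 10.8 ± 1.82 TPM, and Ccdc152 45.9 ± 4.40 and 29.1 ± 1.08 TPM.

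Among those that lay higher were Wdr34, Erf, Maats1os, Trim47, Tmem200b, Spryd3, Plekhh3, Vars2 and Mgat4b, each with a limma Benjamini-Hochberg adjusted p = 0.0893. Erf, a repressor of the ETS family, measured 16.6 ± 2.32 TPM with vehicle and 31.8 ± 2.47 TPM with rMANF (log2 difference 0.91 ± 0.12, SE), the dynein component gene Wdr34 28.0 ± 3.04 and 48.1 ± 0.922 TPM, Plekhh3 11.5 ± 1.70 and 20.6 ± 1.11 TPM, and the mitochondrial valyl-tRNA synthetase gene Vars2 10.6 ± 1.01 and 17.7 ± 0.796 TPM. Trim47, Spryd3, Mgat4b and Tmem200b differed by 0.53 to 0.66, and for Trim47, Mgat4b and Tmem200b part of this followed GC content (below). Maats1os (chromosome 16, 38302616 to 38305020), annotated as antisense, was listed at 0 TPM in all 3 vehicle libraries and at 16.8, 3.68 and 8.24 TPM in rMANF replicates 1, 2 and 3. Its reads cannot be told from those of an overlapping gene on the other strand.

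**Figure D2:**
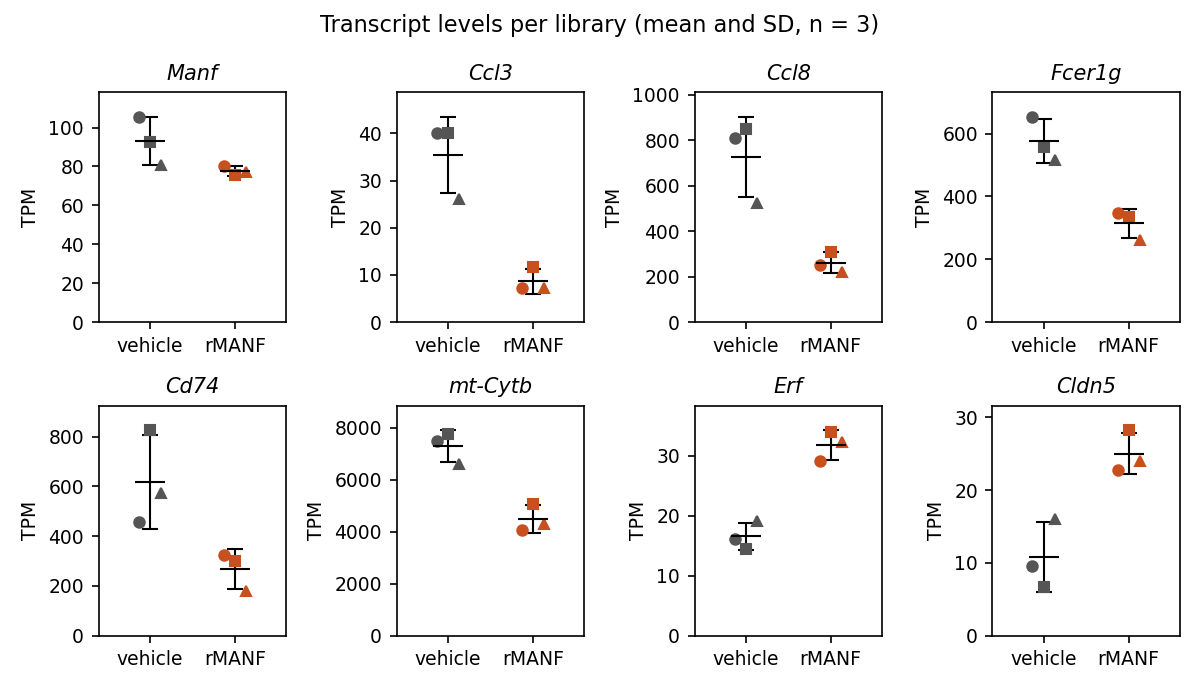
TPM of 8 genes in the libraries labelled vehicle (grey) and rMANF (orange), with the mean and SD of 3 libraries in black and symbol shape for the replicate number. Ccl3, Ccl8, Fcer1g, Cd74 and mt-Cytb lie lower in all 3 rMANF libraries, Erf and Cldn5 higher, and Manf differs by −0.25 on the log2 scale.

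Camera called 17 of the 42 gene lists, 14 lower and 3 higher with rMANF, and 0 with an estimated correlation (lowest adjusted p = 0.519). Fry called 0 (lowest adjusted p = 0.176). All 17 medians kept their sign under median-of-ratios and quantile scaling. So did the 16 lists other than the mitochondrially encoded genes after rescaling without mitochondrial and haemoglobin genes, and 10 of the 17 lists were called in each of the 6 fits that left out 1 library. The vehicle libraries also held more skeletal muscle RNA than the rMANF libraries, unevenly. The 20 skeletal muscle markers summed to 117, 1278 and 30.6 TPM in vehicle replicates 1, 2 and 3 and to 20.7, 10.0 and 8.64 TPM in rMANF replicates 1, 2 and 3. With the level of these markers as a covariate, a fit chosen after seeing the data, 4 of the 17 lists stayed called: macrophage and monocyte markers, inflammatory cytokines and chemokines, mitochondrially encoded genes, and the ATF4 list. That level was higher in every vehicle library than in every rMANF library, so the covariate also takes up part of the group difference. A call that ended with it therefore cannot be laid to muscle.

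**Figure D3:**
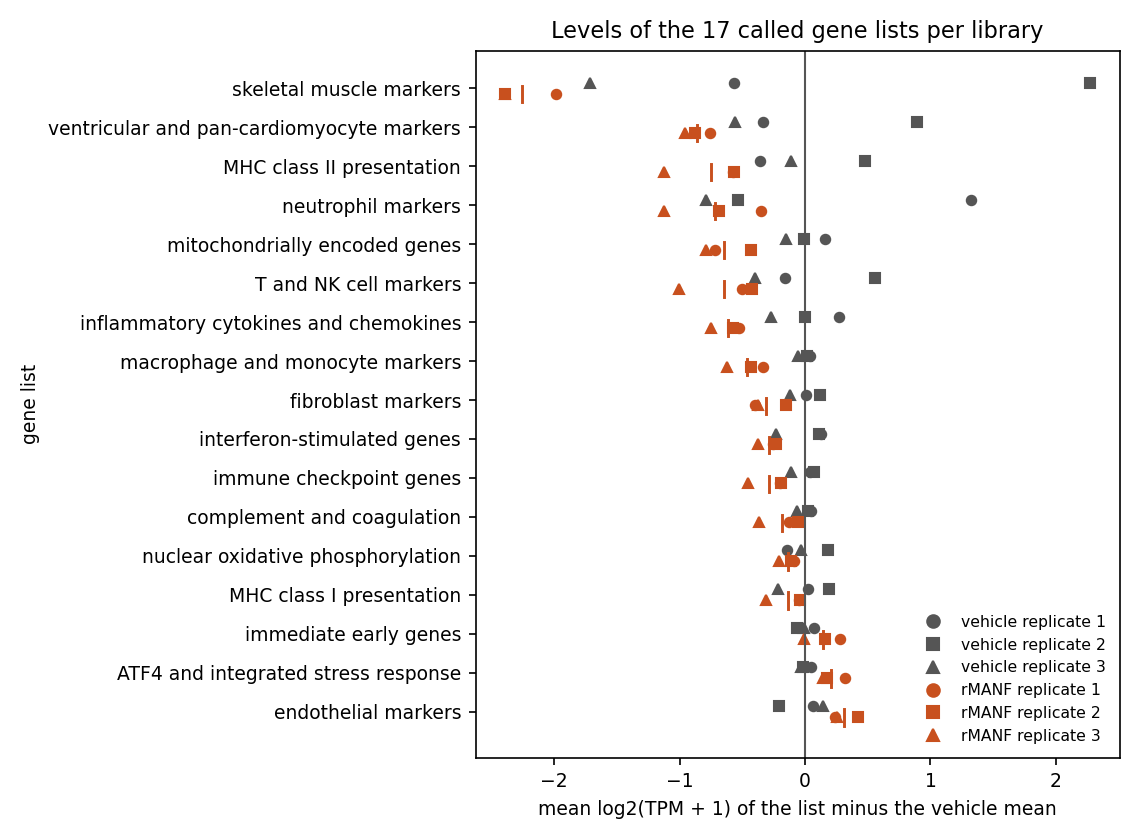
Mean log2(TPM + 1) of the members of each of the 17 called gene lists per library, as the difference from the mean of the vehicle libraries (grey, vehicle; orange, rMANF; symbol shape, replicate number; orange bars, rMANF means). Macrophage markers differ by −0.46 on average with little spread among vehicle libraries, and skeletal muscle markers spread widely among them.

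Macrophage and monocyte markers had a median log2 difference of −0.47 (camera, adjusted p = 1.72e-12; adjusted p = 0.519 with an estimated correlation). Of 33 measured members 31 lay lower and 2 higher, the latter with all rMANF values above all vehicle values. Over all genes tested 0 passed limma's threshold, and 17 passed adjusted over the list alone. Fcer1g led them, followed by Aif1, an actin-binding protein of macrophages (151 ± 21.6 and 83.5 ± 11.1 TPM), and the Fc receptor gene Fcgr3 (94.9 ± 17.3 and 54.8 ± 5.49 TPM). As a mean over members the list stood at 6.42 ± 0.0509 log2 units with vehicle and 5.95 ± 0.148 with rMANF (SD, n = 3 each), an exact permutation p = 0.1, the smallest this design allows.

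Inflammatory cytokines and chemokines had a median of −0.65 (camera, adjusted p = 3.22e-10; adjusted p = 0.519 with an estimated correlation), with 26 of 29 measured members lower. Limma called 0 members over all genes and 11 adjusted over the list alone. Ccl3, Ccl8 and Ccl4 led this list. Its median was −0.38 without vehicle replicate 1 and −0.27 without vehicle replicates 1 and 2 together.

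All 10 measured genes of MHC class II presentation lay lower (median −0.72; camera, adjusted p = 2.89e-06; adjusted p = 0.519 with an estimated correlation). Adjusted over the list alone 6 passed limma's test, against 0 over all genes. Cd74, the invariant chain, measured 618 ± 190 and 269 ± 79.0 TPM, the peptide editor gene H2-DMa 31.0 ± 8.00 and 18.4 ± 1.02 TPM, and the protease gene Ctss 763 ± 125 and 460 ± 111 TPM. The call ended with the skeletal muscle level as a covariate (median −0.36). The MHC class I list lay lower by less (median −0.14; camera, adjusted p = 0.0360; adjusted p = 0.625 with an estimated correlation). Of its 16 members 0 passed over all genes or adjusted over the list alone. Its call ended with library weights (median near 0), under median-of-ratios (−0.20) and quantile scaling (−0.19), and without vehicle replicate 2 (−0.04) or rMANF replicate 3 (−0.06). It ended as well without the filter, without the variance trend and with robust variances, which left the median as it was. The median was −0.27 without vehicle replicate 3, and its sign turned with the muscle covariate (0.09) and without vehicle replicates 1 and 2 together (0.05). B2m, the invariant light chain, measured 5533 ± 455 and 4531 ± 328 TPM, and the peptide transporter gene Tap2 lay higher (72.2 ± 6.31 and 83.5 ± 2.47 TPM).

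Of the interferon-stimulated genes 38 of 44 lay lower (median −0.26; camera, adjusted p = 4.59e-08; adjusted p = 0.519 with an estimated correlation), and 0 passed limma's threshold over all genes or adjusted over the list alone. Cxcl10 measured 187 ± 16.4 and 128 ± 14.9 TPM, Cxcl9, like Cxcl10 a ligand of the chemokine receptor Cxcr3, 52.5 ± 31.8 and 18.7 ± 5.51 TPM, and the GTPase gene Gbp4 11.8 ± 4.94 and 5.47 ± 1.01 TPM. The median was −0.15 without vehicle replicate 1 and −0.05 with library weights, and the call ended with the muscle covariate (−0.14) and without vehicle replicates 1 and 2 together (median near 0).

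T and NK cell markers lay lower for 23 of 25 members (median −0.72; camera, adjusted p = 1.06e-07; adjusted p = 0.519 with an estimated correlation). Limma called 0 of them over all genes or adjusted over the list alone. Trac, the T cell receptor alpha constant chain, measured 11.6 ± 4.18 and 5.04 ± 1.62 TPM and the NK receptor gene Klrd1 9.18 ± 3.44 and 3.50 ± 1.82 TPM, whereas Cd247, the zeta chain of the receptor, lay higher (3.87 ± 0.389 and 5.58 ± 0.486 TPM). The median was −0.43 without vehicle replicate 2, the library with the most skeletal muscle RNA, and −0.47 without rMANF replicate 3. With the muscle covariate it was −0.17 and no longer called. Immune checkpoint genes had a median of −0.32 over 15 members (camera, adjusted p = 0.0216; adjusted p = 0.519 with an estimated correlation). Limma called 0 over all genes and 1, Cd86, adjusted over the list alone. Cd86 measured 9.5 ± 1.68 and 4.25 ± 1.18 TPM, Ctla4, a receptor for the product of Cd86, 5.11 ± 1.69 and 1.97 ± 1.29 TPM, and Cd274, which encodes PD-L1, 17.3 ± 4.0 and 12 ± 2.48 TPM. This call ended with a filter at a mean of 5 TPM, where the median was −0.02. It also ended with library weights (−0.24), without vehicle replicate 2 (−0.31), under median-of-ratios scaling (−0.37), with the muscle covariate (−0.15) and without vehicle replicates 1 and 2 together (−0.17), and the median was −0.18 without rMANF replicate 3.

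Complement and coagulation genes had a median of −0.30 with 17 of 26 lower (camera, adjusted p = 0.000772; adjusted p = 0.519 with an estimated correlation). Over all genes 0 passed limma's threshold, and 2 passed adjusted over the list alone. They were the anaphylatoxin receptor gene C3ar1 (42.1 ± 1.57 and 29.3 ± 4.77 TPM) and the complement inhibitor gene Serping1 (27.5 ± 9.73 and 12.4 ± 2.75 TPM). Without rMANF replicate 3 the median was −0.19, with library weights −0.18 and without vehicle replicates 1 and 2 together −0.09, and the call ended with the muscle covariate (−0.14). All 12 neutrophil markers lay lower (median −0.64; camera, adjusted p = 0.00319; adjusted p = 0.526 with an estimated correlation). Of these 0 passed over all genes or adjusted over the list alone. The call rested on vehicle replicate 1, without which the median was −0.10. It also ended with library weights (−0.15) and with the muscle covariate (−0.70), and the sign turned without vehicle replicates 1 and 2 together (0.08). S100a9 and S100a8, subunits of calprotectin, measured 120 and 67.0 TPM in that library. They measured 9.5 and 18.4 TPM in vehicle replicate 2, 3.65 and 12.3 TPM in vehicle replicate 3, and 3.38 to 6.56 and 8.30 to 19.5 TPM in the rMANF libraries. Without rMANF replicate 3 the median was −0.34.

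All 13 measured mitochondrially encoded genes lay lower (median −0.70; camera, adjusted p = 5.80e-11; adjusted p = 0.519 with an estimated correlation). Adjusted over the list alone 8 passed limma's test, against 0 over all genes. These transcripts made up 3.81, 3.88 and 3.16% of TPM in vehicle replicates 1, 2 and 3 and 2.11, 2.73 and 2.31% in rMANF replicates 1, 2 and 3. Cytochrome b (mt-Cytb) measured 7294 ± 618 and 4488 ± 532 TPM and the complex I subunit mt-Nd2 3775 ± 487 and 2068 ± 352 TPM. The ATP synthase gene mt-Atp6 (23.7 ± 2.78 and 12.8 ± 2.08 TPM) is uncertain, since near-identical nuclear copies are annotated and its level is far below that of its neighbours. Nuclear genes of oxidative phosphorylation lay lower by less (median −0.10 over 58 members, 36 lower; camera, adjusted p = 0.00292; adjusted p = 0.587 with an estimated correlation). Limma called 0 of these over all genes or adjusted over the list alone. Atp5j measured 405 ± 20.5 and 330 ± 17.5 TPM, Cox7a1, a subunit of muscle, 16.4 ± 8.94 and 4.98 ± 1.73 TPM, and Atp5l 878 ± 28.6 and 713 ± 62.0 TPM. The call ended without vehicle replicate 2 (−0.05) and with the muscle covariate (−0.01), and the median was −0.06 without rMANF replicate 3.

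Skeletal muscle markers had the largest median difference, −2.07, with all 17 measured members lower (camera, adjusted p = 9.78e-09; adjusted p = 0.519 with an estimated correlation). Again 0 passed over all genes or adjusted over the list alone. Skeletal actin Acta1 measured 31.4, 232 and 5.43 TPM in vehicle replicates 1, 2 and 3 and 3.46, 0.339 and 0.343 TPM in rMANF replicates 1, 2 and 3. The fast myosin light chain gene Mylpf measured 20.9, 201 and 10.7 against 8.38, 6.31 and 4.28 TPM. Without vehicle replicate 2 the median was −0.78. Ventricular and pan-cardiomyocyte markers had a median of −0.54 over 20 members, 16 lower (camera, adjusted p = 0.000772; adjusted p = 0.519 with an estimated correlation). Over all genes or adjusted over the list alone 0 passed. The members of smallest p were Cox7a1, Mef2c (2.76 ± 0.216 and 1.58 ± 0.120 TPM) and Csrp3 (11.7 ± 16.4 and 0.132 ± 0.229 TPM), which skeletal muscle expresses as well. Without vehicle replicate 3 the median was −0.81, with a filter at a mean of 5 TPM −1.35, and without vehicle replicates 1 and 2 together −0.03. The call ended with the muscle covariate (−0.01).

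Fibroblast markers moved both ways, with a median of −0.25 over 26 members, 17 lower (camera, adjusted p = 0.00755; adjusted p = 0.519 with an estimated correlation). Adjusted over the list alone 12 passed limma's test, against 0 over all genes. The growth factor binding protein gene Igfbp6 lay higher (166 ± 18.5 and 268 ± 27.9 TPM), and decorin (Dcn, 35.6 ± 9.81 and 14.1 ± 4.25 TPM) and Serping1 lay lower. The call ended with a filter at a mean of 5 TPM, where the median was −0.08. It also ended without vehicle replicate 2 (−0.22), with the muscle covariate (−0.23) and without vehicle replicates 1 and 2 together (−0.11), and the median was −0.16 without vehicle replicate 1.

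Endothelial markers lay higher with rMANF for 23 of 26 members (median 0.26; camera, adjusted p = 0.00170; adjusted p = 0.526 with an estimated correlation). Limma called 0 over all genes and 1 adjusted over the list alone, the tight junction gene Cldn5 (10.8 ± 4.78 and 25.0 ± 2.84 TPM). The receptor gene Tie1 measured 3.57 ± 0.981 and 6.15 ± 0.424 TPM and Cdh5, which encodes VE-cadherin, 10.8 ± 3.11 and 16.6 ± 1.09 TPM. The median was 0.16 without vehicle replicate 2, and the call ended with the muscle covariate (0.11).

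Genes of ATF4 and the integrated stress response lay higher for 19 of 23 members (median 0.17; camera, adjusted p = 0.00518; adjusted p = 0.526 with an estimated correlation). Adjusted over the list alone 2 passed limma's test, against 0 over all genes. These were Ddit4, an inhibitor of mTORC1 (42.4 ± 6.22 and 85.3 ± 25.8 TPM), and the amino acid transporter gene Slc7a5 (98.3 ± 7.88 and 131 ± 9.08 TPM). Phgdh, of serine synthesis, measured 310 ± 38.2 and 388 ± 6.88 TPM. Immediate early genes lay higher for 26 of 35 members (median 0.18; camera, adjusted p = 0.0409; adjusted p = 0.625 with an estimated correlation). Limma called 0 over all genes and 3 adjusted over the list alone, the transcription factor genes Klf4 (9.55 ± 0.884 and 16.0 ± 1.23 TPM) and Klf2 (115 ± 10.2 and 153 ± 10.4 TPM) and the phosphatase gene Dusp1 (48.2 ± 5.5 and 74.8 ± 14.2 TPM).

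Across the 12830 tested genes with a GC value, the log2 difference rose with GC content (Spearman 0.386 across genes, which are not independent replicates), from a median of −0.06 in the lowest of 5 GC bins to 0.20 in the highest. Vehicle replicate 1 carried much of this trend. Without it the correlation was 0.214 and the lowest and highest bins had medians of 0.03 and 0.18. Per library, the deviation from the mean of all libraries correlated with GC content at −0.511, −0.05 and −0.01 in vehicle replicates 1, 2 and 3 and at 0.421, 0.135 and 0.306 in rMANF replicates 1, 2 and 3. With each library's GC trend removed, the ATF4 median was 0.10 and the immediate early median 0.01, and neither list was called. Of the genes named above as higher, Tmem200b, Trim47, Mgat4b and Plekhh3, with transcripts of 60.4 to 67.2% GC, then differed by 0.22, 0.31, 0.31 and 0.48, against 0.62, 0.62, 0.53 and 0.79 before. The ATF4 call also ended without vehicle replicate 3 (0.15) or rMANF replicate 1 (0.17), with a median of 0.10 without vehicle replicate 2. The immediate early call ended without vehicle replicate 2 (0.11), vehicle replicate 3 (0.17) or rMANF replicate 1 (0.13), with the muscle covariate (0.08), and without the variance trend or on ranks, which left the median as it was.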

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

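The GC correction, the muscle covariate and the fit without vehicle replicates 1 and 2 together were chosen after seeing the data. The 0 genes called by limma became 737 with library weights (513 higher, 224 lower), 351 at a threshold of 0.10 (249 higher, 102 lower) and 1 with the GC correction (Wfdc17, lower). The fit without vehicle replicates 1 and 2 together leaves 1 vehicle library, which is assumed to vary like the others. Its count of calls is therefore not given. The counts with 1 library left out ran from 0 to 4, from 0 to 1 higher and from 0 to 3 lower. In the main setting 2642 genes had an unadjusted p under 0.05, and 838 did with the muscle covariate. The 17 gene lists called by camera became 0 with an estimated correlation, 0 by fry and 5 with the muscle covariate. The cause of these shifts was not tested. With 1 library left out camera called 13 to 20 lists.

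The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at −0.069, 0.029 and 0.049, and rMANF replicate 1 correlated best with vehicle replicate 2 (0.12). With the number as a block limma called 3 genes, all lower, Ccl3, Ccl8 and mt-Nd1, and camera called 22 lists.

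The MHC class I median turned to 0.088 with the muscle covariate and 0.053 without vehicle replicates 1 and 2 together, where the neutrophil median turned too, from −0.64 to 0.084. With the muscle covariate the direction of camera's test also turned for the ventricular (median −0.0094), skeletal muscle (0.062) and nuclear oxidative phosphorylation (−0.0083) lists, the covariate being made from the muscle list itself. The Hspa5 difference, near 0 throughout, was above 0 with quantile normalization (0.028), library weights (0.050), without vehicle replicate 1 (0.13) or rMANF replicate 1 (0.045), with the GC correction alone (0.037) or with the block (0.037) and without vehicle replicates 1 and 2 together (0.075), and with 1 library left out it ran from −0.11 to 0.13; the cause was not tested. Of the other results of the 17 lists, 326 kept direction and side of the threshold and 75 lost the call, the neutrophil result above among them. Of those of the 26 named genes 547 kept both and 43 passed the threshold. These passes include the threshold of 0.10, which all genes named for small p met in advance with their limma adjusted p of 0.0893. The rest came with library weights, except Ccl3 and Ccl8 with the block and Wfdc17 with the GC correction. Over all alternatives the medians that moved least in proportion were those of macrophage and monocyte markers (−0.55 to −0.39) and mitochondrially encoded genes (−0.84 to −0.56). Those of the other 15 lists moved further in proportion: inflammatory cytokines and chemokines −0.71 to −0.27, MHC class II −1.05 to −0.36, MHC class I −0.27 to 0.088, interferon-stimulated genes −0.38 to near 0, T and NK cells −0.94 to −0.17, immune checkpoint genes −0.37 to −0.019, complement and coagulation −0.38 to −0.090, neutrophils −0.90 to 0.084. Ventricular markers ran from −1.35 to −0.0094, skeletal muscle from −3.63 to 0.062, nuclear oxidative phosphorylation from −0.15 to −0.0083, fibroblasts from −0.35 to −0.083, endothelial markers from 0.11 to 0.33, ATF4 from 0.097 to 0.24 and immediate early genes from 0.013 to 0.21. TPM keeps no depth, so what depth limits is unknown.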

Other observations

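Of the tests weighed here, those on the tissue and on the share of the main cell type were chosen after the result was seen, as were the fits with the muscle covariate and the GC correction.

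For several lists that camera did not call, members of small p are given here as values (SD, n = 3 each), not as a result about the lists. Over all tested genes the groups did not overlap for 27.95%. Wholly above and wholly below vehicle lay 3 and 0 of 19 clock genes, and 5 and 1 of 19 glucocorticoid-responsive genes. The counts were 7 and 2 of 24 for glycolysis, 5 and 3 of 28 for oxidative stress and 10 and 9 of 39 for the matrix. Per1, of the circadian clock and a glucocorticoid-responsive gene, measured 8.58 ± 2.68 TPM with vehicle and 20.3 ± 2.99 TPM with rMANF. The glycolysis list held Slc16a3, a lactate exporter (145 ± 10.2 and 200 ± 7.17 TPM), Pfkl (65.3 ± 7.39 and 87.8 ± 2.74 TPM) and the glucose transporter gene Slc2a1 (99.97 ± 8.03 and 126 ± 9.79 TPM). Among genes of oxidative stress the peroxiredoxin gene Prdx1 lay lower (773 ± 33.7 and 598 ± 21.8 TPM), as did haem oxygenase Hmox1 (223 ± 71.9 and 118 ± 7.93 TPM), while Txnrd1 lay higher (92.3 ± 6.83 and 113 ± 3.58 TPM). The matrix list split, with biglycan (Bgn, 50.9 ± 11.9 and 25.8 ± 5.74 TPM) and Col5a2 (11.6 ± 2.09 and 6.24 ± 1.94 TPM) lower and basement membrane collagen Col4a2 higher (52.5 ± 11 and 80.0 ± 5.48 TPM), and 15 of its 39 members passed limma's test adjusted over the list alone against 0 over all genes. Camera's adjusted p was 0.166 for the clock list, 0.328 for the glucocorticoid list, 0.108 for glycolysis, 0.164 for oxidative stress and 0.0899 for the matrix.

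The growth factor gene Igf1, in the oestrogen-responsive list, lay lower (6.27 ± 0.657 and 3.39 ± 0.497 TPM), but that list as a whole had a median of 0.10 and a mean of −0.04 (camera, adjusted p = 0.738). Cell cycle genes had a median of 0.03 over 35 members and camera's direction was lower (adjusted p = 0.591), while Mcm5, of the replication helicase, measured 54.0 ± 3.56 and 72.2 ± 1.30 TPM. Xist, the RNA that silences an X chromosome in female cells, measured 11 ± 1.33 and 5.86 ± 0.733 TPM.

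The number of limma calls could not be set against chance, since the 6 libraries have only 10 splits into 3 and 3, and all 10 gave at least the 0 genes of the real split (highest other, 1). The real split stood higher at looser limits, with 351 genes at an adjusted p of 0.10 against at most 1 in another split, and 2642 at an unadjusted p under 0.05 against at most 921. The 351 fell to 0 after rescaling without mitochondrial and haemoglobin genes, without the variance trend and with the muscle covariate, and to 1 without the filter or with the GC correction. It was 0 without vehicle replicate 2 or rMANF replicate 2 or 3, 3 without rMANF replicate 1, 971 without vehicle replicate 1 and 538 without vehicle replicate 3. For the lists, 6 of the 10 splits, the real one included, gave at least its 17 camera calls (highest other, 20; lowest, 8), so that number did not stand out among them. The 10 splits are too few for a share under 0.05.

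The near absence of most heart muscle transcripts, Nppb (46.6 to 57.4 TPM) being an exception, was tested against 2 explanations. Rows missing from the table are argued against by the 9 cardiac genes of the contractile apparatus and myoglobin, which all have rows and reached at most 23.5 TPM in any library. Pigmented melanoma cells as the tissue are argued against by Pmel, at most 0.341 TPM in a library. The pigment genes Tyr, Dct, Tyrp1 and Mlana were looked for and had no row among the 23494 listed genes. Every listed gene had a value above 0 TPM in some library, but why these have no row is not given. The wider melanocyte and melanoma list, with 10 of its 15 genes in the table, summed to 117 to 213 TPM. Gpnmb, a macrophage marker too, held 85.5 to 181 TPM of that, Slc24a5 18.1 to 41.6 TPM and Mitf 7.36 to 12.2 TPM, while Sox10, Oca2, Gpr143, Trpm1 and Rab38 reached at most 0.160 TPM. Melanoma cells without pigment stay open. Whether another tissue was sequenced, and whether the labels or the table are at fault, was not tested and stays open.

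Macrophage, chemokine and MHC class II genes, 72 members pooled, had a median log2 difference of −0.56. After removal of the GC trend it was −0.57, which argues against that trend as the whole cause. Without vehicle replicate 2, the library with the most skeletal muscle RNA, it was −0.52. That fit cannot decide on muscle, since the skeletal muscle median was still −0.78 in it. With the muscle covariate the macrophage median was −0.42, the chemokine median −0.44 and the MHC class II median −0.36, and only the last call ended. Without vehicle replicates 1 and 2 together these medians were −0.51, −0.275 and −0.61. A lower share of the main cell type in the vehicle libraries would raise markers of other cell types there alike. The pooled members minus the endothelial markers differed by −0.87 between groups (SDs 0.287 and 0.166). This gap cannot decide, since the endothelial list was chosen after the result was seen and was the only cell type list called higher. Fibroblast (median −0.25) and T and NK cell markers (−0.72) lay lower with rMANF, as that explanation would have it. Also called lower were neutrophil (−0.64), skeletal muscle (−2.07) and ventricular markers (−0.54). Xist lay lower too, but whether the main cell type expresses it is not known here. Endothelial markers (0.26) went the other way, and the explanation stays open. Of the cell type lists that camera did not call, B cell markers had a median of −0.32 (camera, adjusted p = 0.072). Red cell markers had −0.28 (adjusted p = 0.108), brown adipocyte markers −0.21 (adjusted p = 0.0764) and smooth muscle markers −0.08 (adjusted p = 0.242). Atrial (−0.05, adjusted p = 0.115) and thymocyte markers (−0.002, adjusted p = 0.111) lay near 0. White adipocyte markers lay higher, at 0.33 (adjusted p = 0.253). Whether there were fewer or less active myeloid cells with rMANF was not tested and stays open, and the tissue is in doubt. What the control mice received is in doubt too, since the column names of the vehicle samples begin with IgG. Whether this bears on these genes was not tested.

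Mitochondrially encoded genes had a median of −0.70, and −0.58 after removal of the GC trend, while 732 nuclear genes in the same GC range had a median of −0.10. Skeletal muscle is rich in mitochondria, but vehicle replicate 3, with the least muscle RNA of the vehicle libraries, still exceeded the highest rMANF library by 0.28 log2 units (rMANF SD 0.189). With the muscle covariate the median was −0.56. Neither value sets muscle aside, since the muscle marker level was higher in every vehicle library, replicate 3 included, than in every rMANF library. As a sign of RNA handling, the list of nuclear-retained and unpolyadenylated RNAs had a median of 0.17 over 12 members, 8 higher, and was not called (camera, adjusted p = 0.711). Its mean level did not overlap between groups, at 5.43 ± 0.0318 log2 units with vehicle and 5.63 ± 0.136 with rMANF (exact permutation p = 0.1, the smallest this design allows). Limma called 0 of its members over all genes and 2 adjusted over the list alone. Members went both ways: Lars2 (56.9 ± 12.9 and 127 ± 58.9 TPM) and Rpph1 (66.9 ± 31.1 and 145 ± 85.6 TPM, groups overlapping) lay higher and Xist lower. Lars2, annotated as protein coding, was put on this list before the data were examined and counts toward the mean above. What its level says of RNA handling was not tested. A difference in RNA quality or handling between the groups stays open, and an effect of rMANF could not be separated from it.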
